A study of Mus musculus with 6 samples.

How the data were processed

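RNA was measured in 6 libraries, 3 of each of 2 genotypes of mouse Th17 cells, made from 100 ng of RNA with a stranded poly(A) kit, per the labels' protocols. The submitters' processing notes name TopHat2 2.1.1, HTSeq 0.11.1, DESeq2 1.22.2 and the genome build mm10, without saying which step each served. The gene models, the counting settings (strand included) and any filter are not given in the sources used here, so overlapping and antisense genes and near-identical copies are uncertain, as reads can be split or lost between them.

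The deposited table holds a normalised signal per gene and library, taken to be read counts that the authors divided by a size factor per library. The table itself bears this out: in every column 100% of the values above 0 were whole multiples, within 0.01, of a single step, and the column sums were nearly equal (21968377.9 to 22457890.8). The step was 0.433, 0.504 and 0.969 in Stat3C and 1.37, 1.07 and 0.995 in Stim1KO Stat3C. Dividing by the step gave back whole reads, 16009755 to 51347367 per library, a 3.21-fold range. For Stim1KO Stat3C replicate 3 the step lies so close to 1 that an automatic test cannot tell it from rounding, so the count test was also run without that library. A value of 0 allows up to 3 reads, which is 1.30 to 4.11 normalised counts depending on the library, and this limit covers counting error only.

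The table has 23420 rows. In 27 of them the gene name had been turned into a date, as a spreadsheet does, and these rows, at most 0.217% of the reads of a library, stayed out of every test. None of the 13 protein genes of mitochondrial DNA could be matched to a row. Positions were taken from GENCODE mouse release 21 (GRCm38), in which 98.3% of the rows were found by current or older symbol.

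The test was fixed before the data were examined: limma with a variance trend on log2(value + 1), two-sided, all 6 libraries and no covariate, for the 11947 genes with a mean of at least 10 normalised counts, with Benjamini-Hochberg adjustment over these genes. Because the values are counts already scaled by the authors and not raw counts, count models were used only as alternatives, on the recovered reads, where edgeR called 1507 genes, 1478 of them among the 1623, and DESeq2 2250, and edgeR without Stim1KO Stat3C replicate 3 called 922. The coefficient of variation between libraries of a group estimated from those reads was 20.8%. The labels give no batch and no pairing, and replicates were numbered in accession order.

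Lists of genes were written at the same stage: 51 lists, plus the union of the nuclear-encoded subunits of complexes I to V. Of 1009 list members 979 were found in the table, 14 of them by an older symbol. The 48 lists with at least 3 measured members were tested with camera (preset correlation 0.01), with camera using an estimated correlation and with fry, each adjusted over the 48. Camera called 26 lists, 11 higher and 15 lower, and none of them held with an estimated correlation (smallest adjusted p = 0.416). Fry called 12, of which 11 were among the 26. Camera compares a list with all other genes, whereas fry asks whether the members move on balance in 1 direction.

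Genes were named by a rule fixed at the same time. It takes 11 genes always given, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 50 and no overlap between groups, and up to 4 members per list past the threshold by smallest adjusted p, or up to 2 by highest mean where none passed. It gave 162 genes, 149 of them past the threshold. Members named to complete a count of 5 or fewer (Mrpl33, Nr4a2, Cxcl10, Gata3, Stat6, Cish, Cebpd, Cd28 and those given so in the closing section), and Il2, Cd74, Cd22, Cd79b, Ncr1, Klrb1c, Klre1, Klra7, Ddx3y, Kdm5d and Uty, fall outside the rule and were chosen after their values were seen.

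The steps were tested on simulated data drawn for the 11947 genes of this comparison. Of 50 genes simulated at each size, 34% were called at a log2 change of 0.5, 68% at 1, 90% at 2 and 98% at 3, and 2 of 150 calls were false. A further 30 genes were moved by -0.3 as a list. Simulated genes varied independently of each other, with a spread set by expression level alone, and no library stood apart. The rates in the real data can therefore differ. Alternatives covered the pseudocount, the filter, the scaling, the variance prior, edgeR, DESeq2 and voom on recovered reads, and leaving out each library. Thinning to equal depth, Xist as a covariate, library quality weights and edgeR without Stim1KO Stat3C replicate 3 were added after the data were seen. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. A chi-square test of the recovered reads found every pair of libraries to differ by far more than sampling noise (8.70 times at least), so none was counted as a copy of another.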

Results

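Poly(A) RNA was sequenced from mouse T cells grown as pathogenic Th17 cells, the interleukin-17-producing helper T cells that arise when IL-23 is present. Naive CD4 T cells of C57BL/6 mice had been activated through CD3 and CD28 for 2 days with IL-6, IL-1b and IL-23. Both genotypes carried Stat3C, a constitutively active form of the transcription factor STAT3 that is switched on once the Cre recombinase, expressed from the Cd4 promoter, removes a stop sequence. In the group called Stat3C here, this was the only allele changed by Cre. In the group called Stim1KO Stat3C, Cre also removed the floxed part of Stim1, whose protein senses calcium in the endoplasmic reticulum and opens the store-operated calcium channels of the plasma membrane. Each group had 3 libraries. The deposited values were read counts per gene divided by a size factor per library, and the reads recovered from them came to 51347367, 43532417 and 23092044 in Stat3C replicates 1, 2 and 3 and to 16009755, 20660749 and 22519269 in Stim1KO Stat3C replicates 1, 2 and 3. All values below are normalised read counts, given as mean ± SD with n = 3 per group. Fold changes are Stim1KO Stat3C minus Stat3C on the log2(value + 1) scale, so they understate the change of genes with low counts. The sources used here do not say whether the replicates came from separate mice. Xist and Y-linked genes (given below) set replicate 3 of each group apart from replicates 1 and 2, so each group held cells of more than 1 mouse. Whether replicates 1 and 2 came from separate mice is not known. The p-values measure the spread between these samples, which may be technical in part.

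The comparison asked how the transcriptome of these cells changed when Stim1 was deleted, and the series title names mitochondrial metabolism as the process of interest. Stim1 (chromosome 7, 102267806 to 102437319, plus strand, GRCm38) fell from 1966 ± 33.9 to 764 ± 67.2 normalised counts, a log2 fold change of -1.37 (SE 0.08, adjusted p = 0.000287). Its 3 values in Stim1KO Stat3C were 811, 794 and 687, and its 3 values in Stat3C were 1999, 1969 and 1931. The count covers the whole gene, and which exon was floxed is not given in the sources used here, so the reads that remained can include transcripts without the deleted part. How much intact transcript was left, and how far the protein was lost, cannot be told from this count. Stim2, the paralogue of Stim1, stood at 920 ± 78.5 and 1022 ± 10.4 (log2 fold change 0.15, SE 0.08, adjusted p = 0.216). Orai1, the pore subunit of the channel, stood at 846 ± 78.2 and 992 ± 105 (0.23, SE 0.10, adjusted p = 0.167). Stat3 itself stood at 21254 ± 496 and 20945 ± 445 (-0.02, SE 0.05, adjusted p = 0.782), and reads of the Stat3C transgene and of the endogenous gene are not separated in this count. Of 11947 genes tested, 1623 (13.6%) passed an adjusted p of 0.05, 1030 of them higher and 593 lower in Stim1KO Stat3C. A log2 change of at least 1 in size was found for 276 of the higher and 78 of the lower genes. In all 1623 genes the 3 values of the groups did not overlap. Over all tested genes 35.6% did not overlap, against 10% by chance. The count of changed genes rested on single libraries: it was 617 and 651 without Stat3C replicates 1 and 3, 686 and 775 without Stim1KO Stat3C replicates 1 and 2, and 2899 without Stat3C replicate 2, which stood apart from the rest. It was 827 with limma without a variance trend and 3959 with library quality weights.

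**Figure D1:**
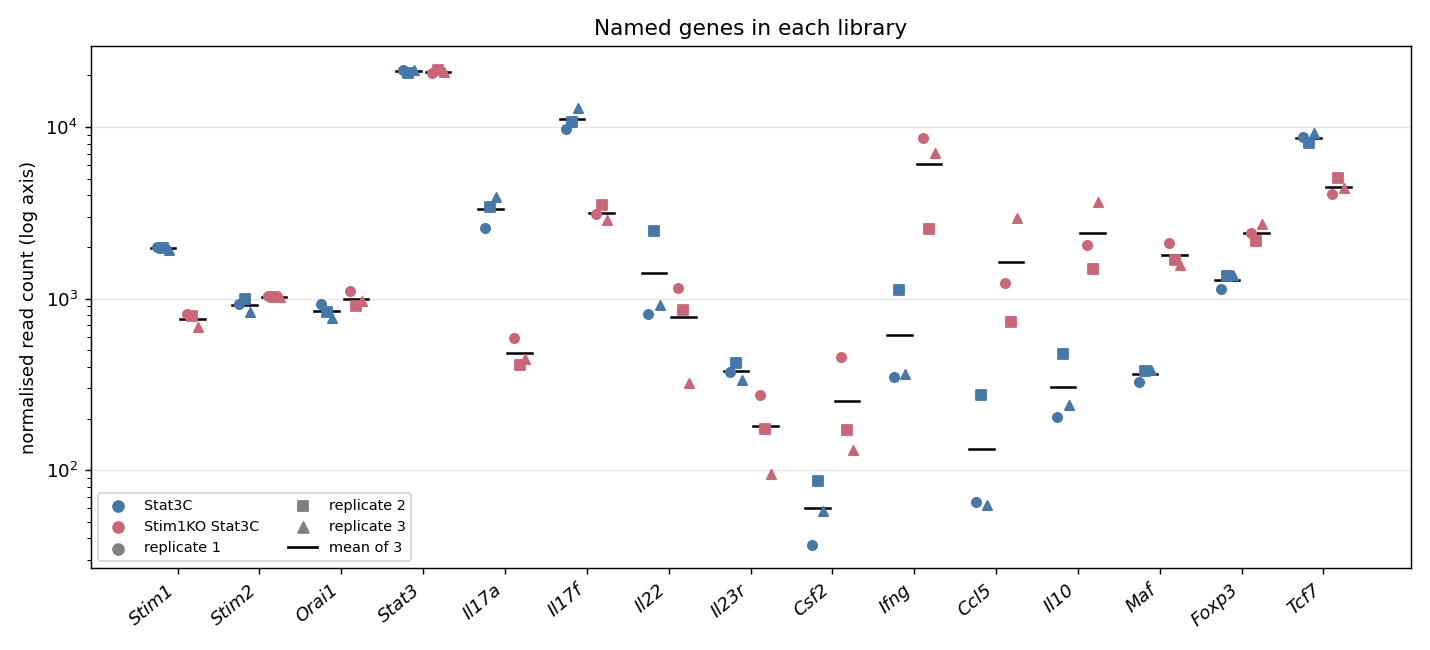
Normalised read counts (log axis) of 15 named genes in each library, with Stat3C in blue and Stim1KO Stat3C in red, a marker shape per replicate number and a black line at the mean of 3. Stim1, Il17a, Il17f and Tcf7 lie lower and Csf2, Ifng, Ccl5, Il10, Maf and Foxp3 higher in every Stim1KO Stat3C library than in any Stat3C library, and Stat3 lies at 21254 and 20945 on average.

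Some genes of the mitochondrion fell by small amounts in Stim1KO Stat3C. Of 78 proteins of the mitochondrial ribosome, which translates the respiratory chain subunits encoded by mitochondrial DNA, 19 fell, 1 rose and 58 did not pass the test, with a median log2 fold change of -0.20. Adjusted over the list alone, 31 fell and 1 rose. Mrpl34 fell from 1097 ± 44.9 to 820 ± 8.09 (log2 -0.42, SE 0.06, adjusted p = 0.00602), Mrpl38 from 1621 ± 107 to 1236 ± 67.4 and Mrpl45 from 2756 ± 141 to 2190 ± 52.5. The member that rose was Mrpl33 (log2 0.26). Of 79 nuclear-encoded subunits of oxidative phosphorylation, 10 fell and none rose, with a median of -0.13 (9 fell adjusted over the list alone), and 71 of the 79 had a negative log2 fold change. These were 4 of 35 subunits of complex I (Ndufab1, Ndufa6, Ndufs7 and Ndufv1, -0.36 to -0.19), 4 of 10 of complex III with cytochrome c (Uqcr10, Uqcr11, Cyc1 and Uqcrc1, -0.32 to -0.20) and 2 of 12 of complex IV (Cox7c at -0.36 and Cox8a at -0.21). Adjusted over each complex alone, the numbers were 3, 8 and 2. Over all genes, Ndufv1 lost its call in 13 of 22 alternative settings and Uqcrc1 in 12, the other named subunits in at most 7 and Cox7c in 0. No subunit of complex II, the succinate dehydrogenase, or of complex V, the ATP synthase, passed the test, alone or over all genes, among 4 and 18 measured. Sdha stood at 6901 ± 151 and 6591 ± 269, and Atp5b at 47795 ± 1721 and 43467 ± 2603. Camera called complexes I, III, IV and V lower (adjusted p = 0.000127, 0.000624, 0.0112 and 0.00247) but not complex II (0.322). With an estimated correlation the adjusted p = 0.491 for complex III and 0.521 for the other 3, and fry called only complex III (adjusted p = 0.0459, against 0.053, 0.0649 and 0.136 for complexes I, IV and V). The 13 genes of mitochondrial DNA are not analysed here.

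Some genes of the tricarboxylic acid cycle and of mitochondrial stress also fell. Of 26 measured cycle and pyruvate dehydrogenase genes, 4 fell and none rose (also 4 adjusted over the list alone). They were Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase (1436 ± 97.8 to 988 ± 80.8, log2 -0.54), Suclg2, Dlat and Idh3a. Dlat and Idh3a each lost their call in 11 of 22 alternative settings, Suclg2 in 5 and Idh2 in 0. Of 12 genes of the mitochondrial unfolded protein response, 6 fell and none rose (8 adjusted over the list alone), with a median of -0.31. Among them were the protease gene Htra2 (1622 ± 149 to 1114 ± 30.4, log2 -0.54), Dnaja3 (log2 -0.38), the chaperonin partner Hspe1 (7153 ± 673 to 5395 ± 351) and the prohibitin Phb (log2 -0.31). By camera, a set test against all other genes, the mitochondrial ribosome (adjusted p = 5.74e-13), oxidative phosphorylation (adjusted p = 9.26e-08), tricarboxylic acid cycle (adjusted p = 0.000134) and mitochondrial stress lists (adjusted p = 0.000183) lay lower. With an estimated correlation between the genes, all 4 calls were lost, at adjusted p = 0.491 for the mitochondrial ribosome and the cycle, 0.521 for oxidative phosphorylation and 0.416 for mitochondrial stress. The self-contained test fry kept the mitochondrial ribosome (adjusted p = 0.0459), the cycle (0.0459) and mitochondrial stress (0.0147) but not oxidative phosphorylation (0.0649). With 1 library left out, 2 to 37 mitochondrial ribosome genes, 1 to 17 oxidative phosphorylation genes, 1 to 6 cycle genes and 2 to 8 mitochondrial stress genes fell, most of them without Stat3C replicate 2.

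**Figure D2:**
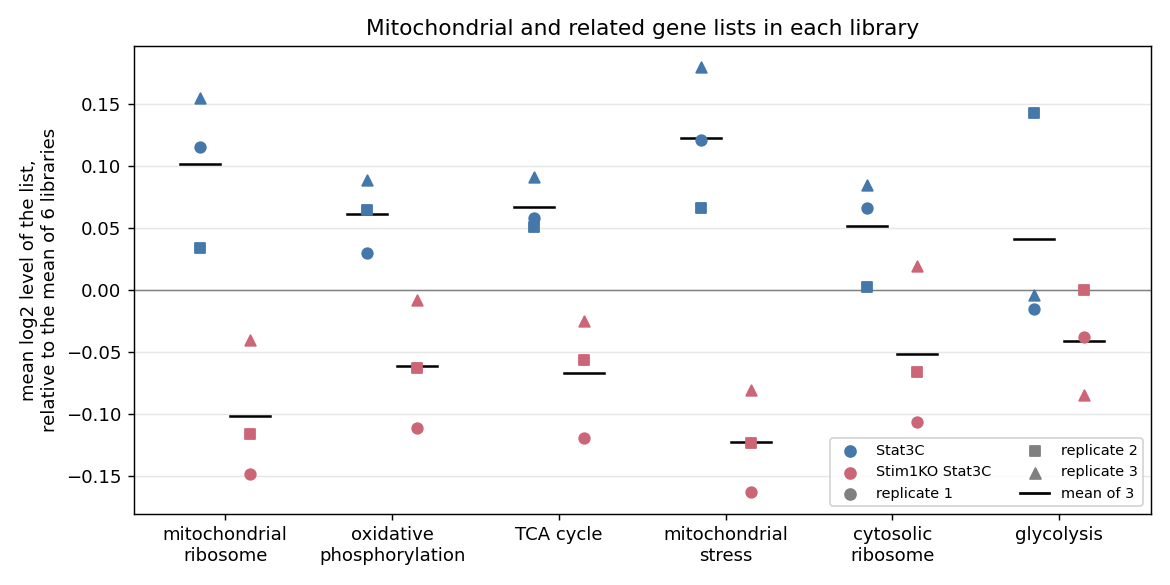
Mean log2 level of 6 gene lists in each library, relative to the mean of the 6 libraries, with Stat3C in blue, Stim1KO Stat3C in red and a black line at the mean of 3. For the mitochondrial ribosome the Stat3C libraries lie at 0.12, 0.03 and 0.16 and the Stim1KO Stat3C libraries at -0.15, -0.12 and -0.04. For glycolysis the list mean of Stat3C replicate 2 lies above the other 5 libraries.

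Other metabolic lists moved less or in parts. Among 24 genes of glycolysis, Eno2 rose (81.3 ± 3.72 to 148 ± 27.5), Ldhb fell (1026 ± 86.5 to 702 ± 149) and 22 did not pass, with a median of -0.01, and adjusted over the list alone only Eno2 passed. Eci1, an enzyme of fatty acid oxidation, fell (422 ± 26.2 to 280 ± 23.6, log2 -0.59) as the only 1 of 21 in its list. Mitochondrial calcium uptake showed changes both ways among 12 genes, of which 3 rose and 2 fell adjusted over the list alone. Mcu, the pore of the mitochondrial calcium uniporter, rose from 517 ± 12.9 to 706 ± 44.4, Ccdc109b, now called Mcub, a paralogue that dampens the pore, rose from 201 ± 12.5 to 306 ± 38.3, and Vdac1, a channel of the outer membrane, fell from 7400 ± 542 to 5882 ± 333. None of these 3 lists was called by camera (adjusted p = 0.321, 0.185 and 0.96), and for calcium uptake camera pointed down while the median and mean were positive. The list of mitochondrial biogenesis had 1 of 17 genes higher, Pparg at a low level (16.7 ± 1.51 to 72.5 ± 30.3), and that of mitochondrial fusion, fission and removal had 1 higher (Smcr7, now called Mief2) and 1 lower (Chchd3) of 14. Both lists gave the same numbers adjusted over the list alone and were not called by camera (adjusted p = 0.47 and 0.269), and for biogenesis the median was negative and the mean positive.

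Within the Th17 lineage the IL-17 genes fell while other members rose. Il17a (chromosome 1, 20730905 to 20734496, plus strand, GRCm38) fell 6.91-fold in its mean, from 3308 ± 669 to 479 ± 94.2 (log2 -2.78, SE 0.17, adjusted p = 0.000287). Il17f fell 3.52-fold, from 11161 ± 1647 to 3171 ± 334 (log2 -1.81, SE 0.11, adjusted p = 0.000287). Il23r stood at 377 ± 44.9 and 181 ± 90.2 and missed the threshold (log2 -1.17, SE 0.33, adjusted p = 0.0529), and passed it in 9 of 22 alternative settings. Il22 stood at 1406 ± 944 and 778 ± 424 with overlapping values (log2 -0.84, adjusted p = 0.32). Maf (363 ± 31.0 to 1789 ± 293, log2 2.29), the aryl hydrocarbon receptor gene Ahr (338 ± 56.4 to 798 ± 174) and Il21 (2994 ± 297 to 4218 ± 265) rose. Over the 16 measured members of the lineage list 3 rose, 3 fell and 10 did not pass (3 and 4 adjusted over the list alone), and camera did not call it (adjusted p = 0.321).

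Many genes ascribed to pathogenic Th17 cells and to Th1 cells rose. Of 16 pathogenic Th17 genes 8 rose and 1, Stat4, fell (11 and 1 adjusted over the list alone). Of 12 Th1 genes 7 rose and 1, again Stat4, fell (9 and 1 adjusted over the list alone). Ifng, the signature cytokine of Th1 cells, rose 9.90-fold in its mean, from 613 ± 443 to 6069 ± 3145 (log2 3.36, SE 0.55, adjusted p = 0.00764). Csf2, which encodes the cytokine GM-CSF, rose from 60.5 ± 25 to 252 ± 176 (log2 1.91, SE 0.48, adjusted p = 0.0357) and lost its call in 7 of 22 alternative settings. The chemokine genes Ccl3 (783 ± 423 to 6907 ± 4155), Ccl4 (1286 ± 443 to 7861 ± 5368) and Ccl5 (133 ± 120 to 1635 ± 1165) rose, as did the receptor genes Cxcr6 (180 ± 86.5 to 1668 ± 459) and Ccr2 (99.0 ± 42.5 to 707 ± 204). Among the transcription factors, Eomes (17.8 ± 4.16 to 175 ± 83.4) and Hlx (69.2 ± 21.4 to 344 ± 61.1) rose, and Stat4 fell from 2174 ± 55.0 to 1348 ± 98.6 (log2 -0.69). Of 26 chemokine, chemokine receptor and integrin genes, 10 rose and 3, among them Cxcl10 and Ccr7, fell (14 and 4 adjusted over the list alone). Camera called the pathogenic Th17 (adjusted p = 0.00151), Th1 (0.000448) and chemokine lists (0.00106) higher. With an estimated correlation these calls were lost, at adjusted p = 0.491, 0.416 and 0.521, and fry kept the Th1 list (adjusted p = 0.0147) but not the pathogenic Th17 (0.104) or chemokine list (0.0724). With 1 library left out, 2 to 10 of the pathogenic Th17 genes and 6 to 9 of the Th1 genes rose. The pathogenic Th17 count was 5 without Stat3C replicate 1 or Stim1KO Stat3C replicate 2, 3 without Stat3C replicate 3 and 2 without Stim1KO Stat3C replicate 1.

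Genes of regulatory T cells rose almost as a whole. Of 13 measured, 12 rose, none fell and 1 did not pass (13 rose adjusted over the list alone), with a median log2 fold change of 1.13. Foxp3, their lineage factor, rose from 1286 ± 127 to 2428 ± 285 (log2 0.91, SE 0.10, adjusted p = 0.00209). Lrrc32, which encodes the TGF-beta docking receptor GARP, rose from 602 ± 134 to 1798 ± 185, Il2ra, the high-affinity chain of the IL-2 receptor, from 36902 ± 663 to 54983 ± 287, and Capg from 3278 ± 199 to 5407 ± 539. Of 14 genes induced by IL-2 and STAT5, 9 rose and 1, Bcl2, fell (also 9 and 1 adjusted over the list alone). Socs2 rose from 183 ± 27.9 to 1087 ± 386, Prdm1, which encodes the repressor BLIMP-1, from 535 ± 169 to 2385 ± 239, and Il2rb from 11049 ± 601 to 18422 ± 359. Of 7 genes ascribed to non-pathogenic Th17 cells 4 rose, Maf, Ahr, Ikzf3 (1118 ± 62.7 to 2234 ± 182) and the anti-inflammatory cytokine gene Il10 (307 ± 149 to 2406 ± 1129, log2 2.97), and none fell (4 and 1 adjusted over the list alone). Of 10 Th2 genes 5 rose, Maf, Il10, Gata3, Il13 (271 ± 192 to 1485 ± 830) and Il5 (10.7 ± 6.98 to 113 ± 23.3), and Stat6 fell (7 and 2 adjusted over the list alone). Camera called all 4 lists higher, at adjusted p = 1.89e-11 for the regulatory T cell, 3.24e-05 for the IL-2 and STAT5, 0.00128 for the non-pathogenic Th17 and 0.00277 for the Th2 list. With an estimated correlation none of the 4 was called, at adjusted p = 0.416 for 3 of them and 0.491 for the IL-2 and STAT5 list, while fry kept all 4 (adjusted p = 0.0147 for 3 and 0.0155 for the IL-2 and STAT5 list). With 1 library left out, 10 to 13 regulatory T cell genes and 6 to 11 IL-2 and STAT5 genes rose, and 3 Th2 genes rose when Stat3C replicate 1 or 3 or Stim1KO Stat3C replicate 1 or 2 was the library left out.

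Genes known to need calcium and NFAT moved both ways, with more higher than lower. Of 34 measured, 13 rose, 2 fell and 19 did not pass (16 and 4 adjusted over the list alone), and camera called the list higher (adjusted p = 0.00244, but adjusted p = 0.491 with an estimated correlation), while fry did not call it (adjusted p = 0.0526). Il2ra, Ifng, Ccl3 and Tnfrsf9, which encodes the costimulatory receptor 4-1BB (2910 ± 801 to 7407 ± 1281), were among those that rose. The orphan nuclear receptor genes Nr4a1, an immediate early gene of T cell receptor signalling (2833 ± 196 to 1342 ± 101, log2 -1.08), and Nr4a2 (log2 -0.57) fell. Il2, which encodes interleukin-2, stood at 4914, 1481 and 4930 in Stat3C and 1415, 739 and 1880 in Stim1KO Stat3C and did not pass the test (log2 -1.40, SE 0.50, adjusted p = 0.102). In the list of store-operated calcium entry and its regulators, Stim1 fell and 6 of 16 genes rose (7 and 1 adjusted over the list alone). These included Plcg1 (2927 ± 113 to 3881 ± 117), the IP3 receptor gene Itpr3 (1796 ± 109 to 2582 ± 184) and Atp2b4, a calcium pump of the plasma membrane (3637 ± 670 to 6576 ± 983). Camera called this list higher (adjusted p = 0.0125, but adjusted p = 0.521 with an estimated correlation), and fry did not (adjusted p = 0.127). With 1 library left out, 8 to 15 of the calcium and NFAT genes and 3 to 7 of the store-operated entry genes rose, with 3 of the latter without Stat3C replicate 1 or 3 and 8 of the former without Stim1KO Stat3C replicate 1. Of 18 genes induced by STAT3, 5 rose, Bcl3, Cish, Il10, Il21r and Prdm1, and 3 fell, Cebpd, Fos and Pim2 (8481 ± 462 to 4811 ± 143), with no camera call (adjusted p = 0.612) and 5 each way adjusted over the list alone. Of 14 naive and memory T cell genes 3 fell and 3 rose. Tcf7, which encodes the factor TCF1 (8653 ± 578 to 4501 ± 483), and Ccr7 (5566 ± 230 to 3577 ± 579) fell, while Foxo1, Cd28 and Il7r rose (4 each way adjusted over the list alone, camera adjusted p = 0.221).

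**Figure D3:**
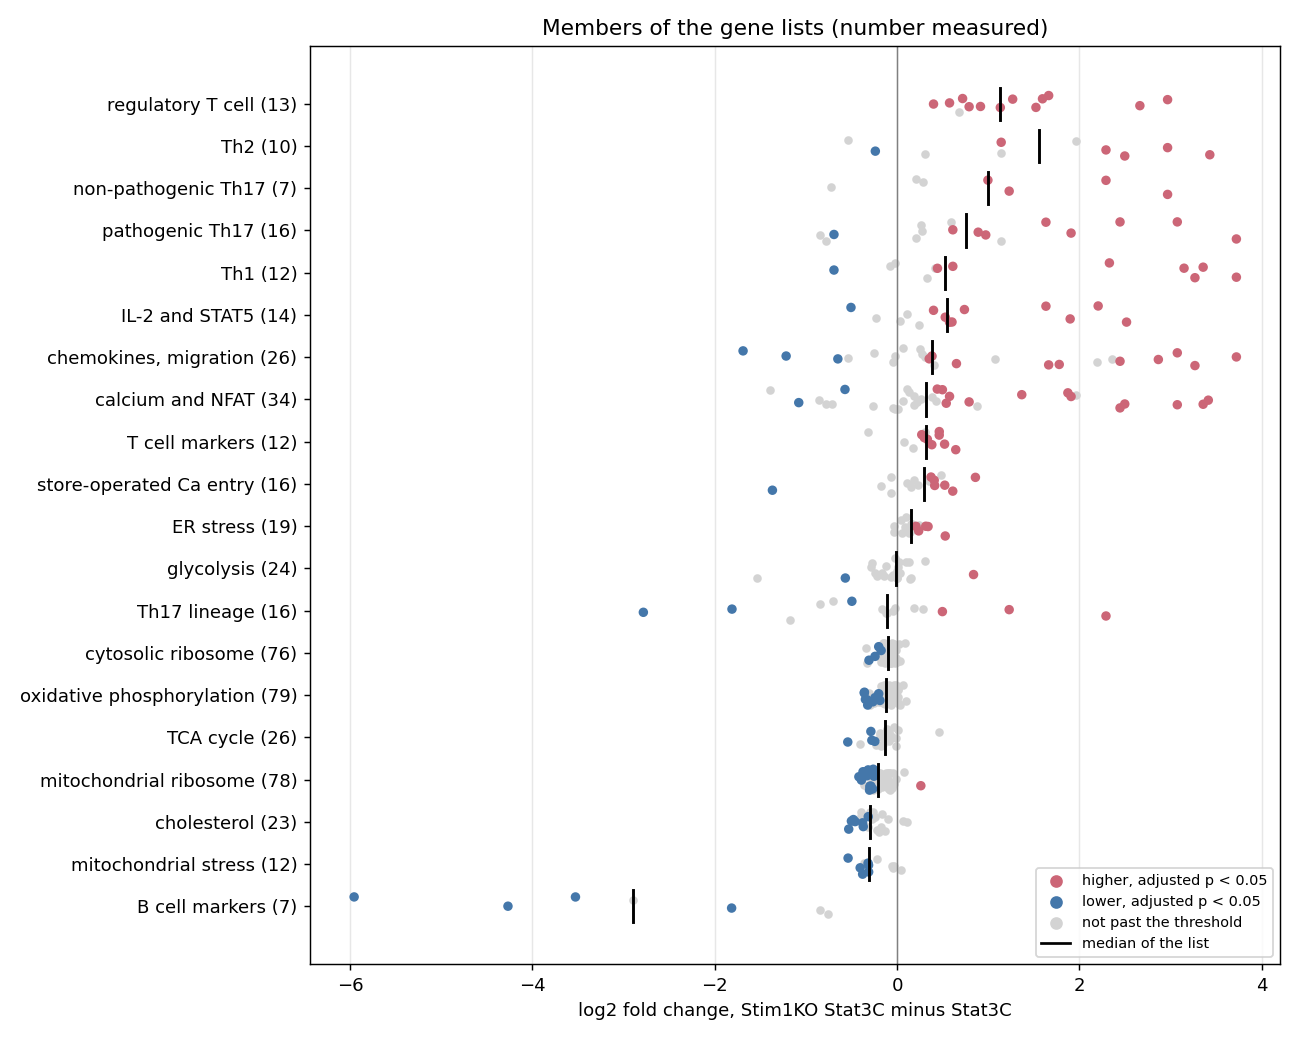
Log2 fold change of every measured member of 20 gene lists, with coloured points past an adjusted p of 0.05, grey points not past it and a black line at the median of each list. The regulatory T cell list lies to the right of 0 with a median of 1.13, and the mitochondrial ribosome and oxidative phosphorylation lists lie just left of 0 with medians of -0.20 and -0.13.

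The largest increases among genes with a mean of at least 50 normalised counts were in Gzmk, a granzyme (0.504 ± 0.872 to 114 ± 78.1), the transcription factor genes Msc (6.68 ± 5.81 to 186 ± 104), Arnt2 (12.2 ± 3.03 to 348 ± 156) and Tfcp2l1 (7.19 ± 4.94 to 104 ± 42.4), the muscle genes Ttn (4.85 ± 4.27 to 126 ± 130) and Myh3 (6.02 ± 2.11 to 114 ± 42.8), Ccl9 (160 ± 198 to 1809 ± 839), Stfa2, Ccl5 and Il5. Among the largest decreases were those in Wdfy4 (321 ± 381 to 9.28 ± 4.999), Cd8a (141 ± 48.9 to 10.04 ± 6.86), H2-Aa (295 ± 386 to 13.7 ± 9.70), Ccl22 (180 ± 95.7 to 15.05 ± 8.91), Tnfrsf13c (98.0 ± 43.9 to 7.93 ± 3.43), Syk (295 ± 231 to 26.6 ± 16.5), Adh1 (152 ± 19.0 to 14.98 ± 0.984), Il17a and Lipg (287 ± 41.4 to 62.8 ± 18.1). Several of these are markers of other cells. Some B cell markers fell, with 4 of 7 measured, among them Blk, Cd79a and Ebf1, past the threshold (5 adjusted over the list alone), at counts that were low beside those of T cell genes such as Cd2 (7266 ± 620 to 11325 ± 191). Camera (adjusted p = 0.000173) and fry (0.0147) called the B cell list lower, and the camera call was lost with an estimated correlation (adjusted p = 0.416). Of 12 T cell markers 8 rose, among them Cd2, Cd5, Cd3d and Lat, and none fell (9 and 1 adjusted over the list alone), and camera called them higher (adjusted p = 3.36e-05, but adjusted p = 0.416 with an estimated correlation), as did fry (adjusted p = 0.0147). With 1 library left out, 2 to 5 B cell markers fell (2 without Stat3C replicate 1 or 3) and 3 to 9 T cell markers rose (3 without Stim1KO Stat3C replicate 1). In the list of natural killer and CD8 T cell markers, Nkg7 (366 ± 127 to 1554 ± 740) and the perforin gene Prf1 (340 ± 192 to 1685 ± 1103) rose, Cd8a and Cd8b1 (243 ± 46.5 to 128 ± 23.5) fell, and 4 of 8 did not pass, with the same numbers adjusted over the list alone and no camera call (adjusted p = 0.598).

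Stat3C replicate 2 differed from the other libraries. Its Pearson correlation across genes was 0.963 and 0.954 with Stat3C replicates 1 and 3, against 0.99 between those and 0.981 to 0.987 among the Stim1KO Stat3C libraries. It held more reads of genes of antigen-presenting cells. H2-Aa stood at 741 in this library against 53.2 and 92.1 in the other Stat3C libraries, and Cd74 at 2158 against 413 and 557. Wdfy4 (759 against 76.6 and 127) and Syk (560 against 139 and 187) were also highest in it. The 27 interferon-stimulated genes had a mean log2 level of 1.25 in it against -0.74 and -0.80, relative to the 6 libraries. Among the Stat3C libraries, Ifng (1124 against 350 and 364) and Ccl5 (272 against 64.9 and 63.0) were highest in it as well. The 3 decreases H2-Aa, Wdfy4 and Syk were smaller but still past the threshold without this library, and lost their calls in 9, 4 and 2 of 22 alternative settings. Among 11 myeloid markers, Cd68 rose (131 ± 13.2 to 359 ± 39.9), H2-Aa fell and 9 did not pass, with the same numbers adjusted over the list alone and no camera call (adjusted p = 0.0939). The myeloid list gained a camera call in 3 of 22 alternative settings. Replicate 3 of each group was the only one with high Xist (8362 and 11549) and had at most 1.99 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, so libraries of both kinds stood in each group in the same numbers. The list of these 5 genes had none past the threshold, over all genes or adjusted over the list alone (camera adjusted p = 0.96), and their median was negative and their mean positive. Malat1 (3862 ± 939 to 10065 ± 3917) and Neat1 (583 ± 132 to 1609 ± 560), RNAs kept in the nucleus, rose, in a list of 9 RNAs that show RNA selection and quality (3 rose adjusted over the list alone, camera adjusted p = 0.47).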

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

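Thinning to equal depth, Xist as a covariate, library quality weights and edgeR on 5 libraries were chosen after the data were seen. Under all 22 alternative settings of the gene test, all of the 1623 changed genes that were still tested kept their direction. For many settings this was fixed in advance, because the values of the groups did not overlap in any of these genes. Leaving out a library, weighting the libraries, or changing the pseudocount or variance prior cannot turn such a direction. Of the 149 named genes past the threshold, 66 kept their call in all 22 settings, among them Stim1, Il17a, Il17f, Maf, Il10, Foxp3, Tcf7, Nr4a1 and Stat4, and 83 lost it in at least 1. Ifng lost it only with the robust variance prior (adjusted p = 0.0561, range over the alternatives 0.000143 to 0.0561).

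The number of changed genes, 1623 (1030 higher, 593 lower), moved by more than 1.5 times under 4 kinds of setting. Without a variance trend it was 827 (603 higher, 224 lower), with edgeR on the recovered reads of 5 libraries 922 (639 higher, 283 lower), and with library quality weights 3959 (2155 higher, 1804 lower). DESeq2 on the recovered reads called 2250 (1246 higher, 1004 lower). With each library left out in turn, the count ranged from 617 to 2899, with 477 to 1707 higher and 140 to 1192 lower. The highest came without Stat3C replicate 2, which has the lowest quality weight (0.369), and the lowest without Stat3C replicate 1. Fewer libraries explain part of the falls by construction, and the other causes were not tested. The share of higher genes was 63.5%, and 55.9 to 63.0% under the 3 other scalings.

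The oxidative phosphorylation list (camera adjusted p = 9.26e-08) stayed lower under every setting of the values (3.92e-10 to 6.38e-06) but lost its call with an estimated correlation (adjusted p = 0.5208) and with fry (0.06495), and the cause was not tested. All 26 lists called by camera kept that call under every setting in which they were tested, which was all 22 except for the B cell list, not tested with a mean of at least 50, 5 lists not called gained a call in some, and no list held with an estimated correlation. At these depths and with 3 libraries a group, simulation called 34% of genes changed by 0.5 on the log2 scale. The simulation also moved 30 genes by -0.3. Its 150 calls comprised 17, 34, 45 and 49 of the genes moved by 0.5, 1, 2 and 3, and 2 false calls. Few calls were thus left for these 30 genes. No call rate was taken for changes under 0.3 in size or for abundant genes alone. How many changes as small as the mitochondrial list medians of -0.20 and -0.13 a test of single genes can call was therefore not measured. Some of that size passed, such as Ndufv1 at -0.19.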

Other observations

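Of 23 genes of cholesterol synthesis and uptake 7 fell and none rose (11 adjusted over the list alone), among them Sqle (2966 ± 226 to 2279 ± 105), Hmgcs1 (4327 ± 603 to 3043 ± 252) and Idi1, with 0 to 19 lower when 1 library was left out. Of 16 genes of fatty acid synthesis 3 fell, Fads2 (706 ± 65.5 to 269 ± 67.0), Elovl6 (2241 ± 79.6 to 1274 ± 235) and Acly, and none rose (4 adjusted over the list alone), with 2 to 8 lower when 1 library was left out. Camera called both lists lower (adjusted p = 5.32e-06 and 0.000448), but with an estimated correlation the adjusted p = 0.521 and 0.514, and fry called neither (adjusted p = 0.127 and 0.0649). Few genes passed in the lists of cell division (5 of 32 fell, Ccne1, Mcm3, Plk1, Cdc20 and Mcm6, also 5 adjusted over the list alone), the cytosolic ribosome (4 of 76 fell, Rpl36, Rplp2, Rps21 and Rpl18, none adjusted over the list alone), MYC and ribosome production (Fbl and Cad fell and Odc1 rose, of 18, the same adjusted over the list alone) and the proteasome (none of 34, alone or over all genes). Camera called these 4 lists lower (adjusted p = 0.000603, 3.72e-07, 0.00239 and 0.00215). With an estimated correlation these had adjusted p = 0.578, 0.585, 0.585 and 0.598, and fry called none of them (adjusted p = 0.164, 0.148, 0.248 and 0.198). With 1 library left out, 0 to 7, 0 to 10, 0 to 11 and 0 to 4 of their genes were lower. In these 4 lists and both lipid lists the highest count came without Stat3C replicate 2 (7, 10, 11, 4, 19 and 8), and all 4 had none lower without Stat3C replicate 1 or 3. The cytosolic ribosome median, -0.10, was -0.04 once the trend with gene length, GC content and mean level was removed. Of 19 genes of the endoplasmic reticulum stress response 5 rose, Sel1l, Pdia4, Hsp90b1, Dnajb11 and Xbp1 (7 adjusted over the list alone, camera adjusted p = 0.000624, adjusted p = 0.521 with an estimated correlation, fry adjusted p = 0.0526), but none of them was called without Stat3C replicate 1, Stat3C replicate 3 or Stim1KO Stat3C replicate 2.

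Other lists were not called by camera, and most held changes in both directions. The antioxidant list gained a camera call in 8 of 22 settings (adjusted p down to 0.0106) and the interferon list in 2 (down to 2.92e-06). So did the myeloid list in 3 (down to 0.0107) and the apoptosis and fatty acid oxidation lists in 1 each (down to 0.0236 and 0.0471). Of 23 antioxidant genes Glrx (916 ± 348 to 5078 ± 330) and Hmox1 rose, and Gpx1 (6537 ± 536 to 4877 ± 192), Gpx4, Prdx2, Prdx3 and Sod2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0527, with a negative median and a positive mean). When 1 library was left out, 1 to 3 antioxidant genes rose and 1 to 6 fell. Among 19 hypoxia-inducible genes Vegfa (777 ± 4.98 to 383 ± 65.9) and Ndrg1 fell and the oxygen sensor gene Egln3 rose (2941 ± 71.4 to 5889 ± 432), also adjusted over the list alone (camera adjusted p = 0.334). Of 24 amino acid and integrated stress response genes Ddit3, Chac1 and Atf3 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.884, with a negative median and a positive mean). Of 17 NF-kB genes 4 rose, Traf1, Bcl3, Icam1 and Rela, and 3 fell, Nfkbiz, Rel and Nfkbie (5 and 4 adjusted over the list alone, camera adjusted p = 0.96). Of 24 apoptosis genes Casp8, Fasl, Birc2 and Cflar rose and Bcl2 fell (3065 ± 40.7 to 2162 ± 127), with 5 and 2 adjusted over the list alone (camera adjusted p = 0.121). When 1 library was left out, 0 to 6 apoptosis genes rose and 1 fell. Of 17 immediate early and heat shock genes Jund and Atf3 rose and Nr4a1, Fos and Hsp90aa1 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.322, fry adjusted p = 0.0459 lower). Among 27 interferon-stimulated genes Gbp4 and Zbp1 rose, also adjusted over the list alone (camera adjusted p = 0.334), and 12 rose without Stat3C replicate 2. Of 8 follicular helper genes Il21, Cxcr5 and Icos rose (3 and 1 adjusted over the list alone, camera adjusted p = 0.196), and of 18 p53 target genes Ei24 alone fell, also adjusted over the list alone (camera adjusted p = 0.945). The neutrophil, gamma delta and red cell marker lists had fewer than 3 measured members and were not tested.

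The tests of the other splits of the libraries for the count of genes, of both mitochondrial lists against the cytosolic ribosome, of length, GC content, level and depth for oxidative phosphorylation, and of Cd8a and Cd8b1 alone were chosen after those results were seen. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many changed genes came from 1 of the 10, the real split, with 1623 genes against a highest of 0 in the other 9, where 91 to 1475 genes had an unadjusted p under 0.05 against 3713. For the oxidative phosphorylation list 2 of the 10 gave a camera p as small, the real p being 5.79e-09 and the smallest other 3.43e-15. For the mitochondrial ribosome list only the real split did so, at 1.2e-14 against 8.87e-14. The other 9 splits had 2 to 23 lists called by camera with its preset correlation, against 26, and none by fry, against 12. Each of these 9 splits mixed both genotypes on each side, which raises the spread within a side, so their low counts of genes and fry calls were in part fixed by the design.

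The fall within the mitochondrial ribosome and oxidative phosphorylation lists was weighed against 3 other readings. After the trend of the fold changes with gene length, GC content and mean level was removed, the list medians were -0.198 and -0.108, at the 0.01 and 1.03 percentiles of 10000 random lists, which argues against these properties as the whole cause, whereas the cytosolic ribosome median moved from -0.10 to -0.04, at the 45.07 percentile. After thinning every library to 16009755 reads, 20 and 9 genes of the lists were called lower, against 19 and 10 before, which argues against the number of reads itself. Every Stat3C library was deeper than every Stim1KO Stat3C library. Differences in preparation or sequencing that go with depth therefore cannot be told apart from genotype. The mitochondrial ribosome median lay below that of the cytosolic ribosome by -0.106, lower than all 10000 random reassignments of the genes. For oxidative phosphorylation the difference was -0.0276, with 3.92% of the reassignments as low. Reassignments and random lists treat genes as independent. The estimated correlation between genes was 0.333 in the mitochondrial ribosome, 0.302 in the oxidative phosphorylation and 0.64 in the cytosolic ribosome list. These shares and percentiles therefore overstate the evidence, and a fall shared with the cytosolic ribosome stays open for both lists. Chance stays open for both lists, as does RNA quality, which was not tested although Malat1 and Neat1 rose, so lower mitochondrial transcript levels without STIM1 remain a hypothesis.

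The loss of B cell transcripts may come from B cells carried over into the Stat3C cultures. The deviations of the 7 markers from their group means had a median pairwise correlation of 0.338, between the 0.5 that a shared source was taken to need and the 0.1 taken to argue against it, and 4.71% of 10000 random lists of genes were as high (random median -0.03). Cd79b (34.7 ± 12.4 and 21.8 ± 13.7) and Cd22 (36.3 ± 11.3 and 21.5 ± 9.04), also B cell genes, did not pass the test while Blk, Cd79a and Ebf1 did, and Cd74, abundant in B cells, stood at 413, 2158 and 557 in Stat3C and 902, 489 and 626 in Stim1KO Stat3C. Cultures started from naive CD4 T cells, whose isolation should leave B cells out. B cells and a change in the T cells cannot be told apart here, as 7 markers at low counts in 3 libraries a group do not decide.

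The rise of Ifng and chemokine genes could come from CD8 T cells or natural killer cells left in the Stim1KO Stat3C cultures, although the cultures started from naive CD4 T cells, whose isolation should leave both out. The markers Cd8a, Cd8b1, Ncr1 and Klrb1c had a median log2 fold change of -0.932 where Ifng had 3.36, but Ncr1, Klrb1c, Klre1 and Klra7 had at most 9.95 counts in any library, too few to speak on natural killer cells. Cd8a and Cd8b1 alone had a median of -2.35, and Cd8a stood at 150, 87.6 and 184 in Stat3C and at 6.85, 5.37 and 17.9 in Stim1KO Stat3C, which argues against CD8 T cells. In the list of natural killer and CD8 T cell markers 6 of 8 had a positive log2 fold change, with Nkg7 and Prf1 past the threshold. Ncr1, Klrb1c, Klre1 and Klra7 lay below the filter and were not among these 8. Klrb1c stood at 0 in every Stim1KO Stat3C library and Ncr1 at 8.22, 1.07 and 0. The list therefore cannot tell natural killer cells from a change within the CD4 T cells, and both stay open.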
